A study of Homo sapiens with 6 samples.

How the data were processed

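MDA-MB-231, a human triple-negative breast cancer cell line, had been given an EGFP-tagged copy of ribosomal protein L10a, a protein of the large ribosomal subunit. In translating ribosome affinity purification (TRAP), beads carrying an antibody to GFP pull down tagged ribosomes together with the mRNAs bound to them. Per the labels' protocols, cells were kept in 0.2% serum for 24 h and then treated for 6 h with the chemokine CXCL12 and the growth factor IGF1 together, and polyadenylated RNA from the pull-down was made into Illumina TruSeq libraries. There were 6 libraries in 3 groups of 2 biological replicates, lettered a and b: untreated cells, a lower dose of 30 ng/mL CXCL12 with 10 ng/mL IGF1, and a higher dose of 300 ng/mL CXCL12 with 100 ng/mL IGF1. Groups and doses were taken from the treatment labels. Total RNA from the same cultures was not analysed here, so a changed share of an mRNA in the pull-down may reflect its abundance, its association with ribosomes, or its recovery. The factors were given together at each dose, so their separate contributions cannot be compared.

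The deposited values were whole-number read counts per gene symbol, 1 file for each library, made by the authors with HTSeq; the submitters' processing notes also name CASAVA 1.8.1, TopHat 1.4.0 and the human build hg19. The gene annotation, the counting mode and whether strand was used in counting are not given in the sources used here. Each file held 21624 lines, of which 21619 were genes and 5 were HTSeq's summary lines. The summary lines were left out of library sizes and tests; they held 9.40% to 10.2% of the reads of a library, including 4.71% to 5.32% outside annotated genes, 1.87% to 2.08% in overlapping genes and 2.62% to 2.88% without a unique position. Reads on genes came to 26255079 to 30280322 per library, where 3 reads correspond to 0.0991 to 0.114 CPM (counts scaled by library size, the usual edgeR unit), the limit that a count of 0 allows. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

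Replicates of each group were compared before they were averaged. Over genes with at least 20 reads, a chi-square comparison of their counts gave 1.98 per degree of freedom for the untreated pair, 1.69 for the lower dose pair and 1.52 for the higher dose pair, so the replicates differed by more than counting noise and each was counted as a sample. The labels call them biological replicates. The comparison cannot test this, as libraries prepared separately from the same culture could also differ by more than counting noise.

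Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, which ranged from 0.997 to 1.003, filterByExpr by group, robust quasi-likelihood fit, two-sided quasi-likelihood F test). All 6 libraries entered 1 fit with 3 group means and 3 residual degrees of freedom. TMM takes most genes as unchanged, so rises and falls are relative to the other genes. A shift shared by most genes would not show. 13548 genes passed the filter and 8071 did not. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, with a threshold of 0.05. Log2 fold changes are given with the standard error that the quasi-likelihood F statistic implies (absolute log2 fold change over the square root of F). CPM are given as mean with SD (n = 2). The estimated biological coefficient of variation was 1.79%, so small fold changes pass the test, and counts at a fold of at least 1.5 are given beside all calls. The p-values rest on this small spread between the libraries of a group. On simulated counts, drawn from the real means and library sizes for the comparison of the higher dose with untreated cells, edgeR recovered 58% of 50 genes changed 1.25-fold, 88% of 50 changed 1.5-fold and 92% of 50 changed 2-fold, with 4.62% of its 173 calls on unchanged genes (13472 genes tested). Far fewer genes were changed in these counts than the 7626 called in the real comparison, in equal numbers up and down. The simulated rates therefore need not hold for the real comparison.

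The 21 gene lists were compiled from general knowledge. Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, correlation between genes preset to 0.01), which compares a list's genes with all others, with Benjamini-Hochberg adjustment over the 21 lists. Camera was also run with a correlation estimated for each list, and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. Counts of list members are given from the adjustment over all genes and adjusted over the list alone. Some genes stand in more than 1 list. Overlap between the doses was set against independent lists and against 100 simulated sets (20 for calls) of unchanged groups. In each set all libraries were drawn anew from the mean over the real ones, and both doses were compared with the same drawn untreated libraries.

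The comparisons, tests, gene lists, named-gene rule and most alternatives were chosen before the data were examined. The rule names, for each dose against untreated cells, the 10 genes that rose and the 10 that fell most among those past the threshold, with a mean of at least 5 CPM and both treated libraries on the same side of both untreated ones; between doses it names 5 and 5. It adds CXCR4, CXCR7, IGF1R, INSR, CXCL12, IGF1 and RPL10A, and up to 4 members of each list with the smallest p. Other list members named where 5 or fewer went against the rest of their list, and those named as examples without being among those 4, were picked after their values were seen. Some genes that the rule names are not reported here. Gene symbols are those of the files, with current symbols in parentheses. The reference used here is GRCh38, a different build from that of the files, and served only for current symbols, transcript and coding lengths and GC content; no coordinates are printed. A transcript length was found for 97.6% of the tested genes.

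Alternatives were DESeq2 1.42.0, DESeq2-style (RLE) size factors in edgeR, no filter on low counts, a filter of at least 5 CPM in 2 libraries, only the 4 libraries compared, the replicate letter as a block, limma voom, the estimated correlation in camera, and each library left out in turn. Chosen after seeing the data were an edgeR fit with offsets per library for transcript length and GC content (splines with 5 degrees of freedom), a fold minimum of 1.5, and libraries thinned to the smallest total. In simulated counts with only a length trend, edgeR called 2555 of 13548 genes without these offsets and 0 with them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.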

Results

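The data describe how polysome-associated mRNAs of MDA-MB-231 breast cancer cells, recovered through EGFP-tagged ribosomal protein L10a, differed after 6 h with CXCL12 and IGF1 from those of untreated, serum-starved cells. Each of the 3 conditions (untreated, lower dose, higher dose) had 2 libraries. Reads on genes ranged from 26255079 (untreated a) to 30280322 (untreated b). The 10 most abundant genes took 4.32% to 4.88% of them. On a principal component analysis of log2 CPM, the first component held 56.9% of the variance and the second 12.9%. The first ordered the libraries as untreated, lower dose and higher dose. The second set the lower dose libraries (−10.5 and −9.93) apart from the untreated (9.12 and 1.03) and higher dose libraries (6.55 and 3.76). Shorter transcripts were relatively more abundant after treatment. Across genes, which are not independent replicates, log2 fold change and transcript length had a Spearman rho of −0.27 at the lower dose, −0.28 at the higher dose and −0.19 between the doses. The shortest 10% of transcripts had a median log2 fold change of 0.19 at the higher dose, and the longest 10% had −0.13.

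The first comparison asks how the lower dose (30 ng/mL CXCL12 with 10 ng/mL IGF1) altered the pulled-down mRNA. FGF1, a fibroblast growth factor, rose 1.65-fold, from 5.25 ± 0.33 to 8.64 ± 0.82 CPM (SD, n = 2 libraries per group; log2 fold change 0.72 ± 0.11 SE, edgeR adjusted p = 4.96e-07). SNHG3, which hosts small nucleolar RNAs (snoRNAs) in its introns, rose by 50.1%, from 82.7 to 124 CPM (adjusted p = 2.81e-18). PBXIP1 fell by 40.5%, from 50.5 ± 1.6 to 30.1 ± 0.97 CPM (adjusted p = 2.52e-17). JUP, the junction protein plakoglobin, fell by 36.4%, and HSPG2, the basement membrane proteoglycan perlecan, fell by 34.5%. The receptor of IGF1, IGF1R, fell by 11.7% (log2 fold change −0.18 ± 0.06, adjusted p = 0.00936), and the insulin receptor INSR fell as well (−0.32 ± 0.08, adjusted p = 0.000987). CXCR4, the receptor of CXCL12, had 47.3 ± 2.8 CPM in untreated cells and 44.8 ± 1.6 CPM at the lower dose and did not pass the test (−0.08 ± 0.05, adjusted p = 0.197). The IGF1R call was lost with DESeq2 at the same fold (−0.18, adjusted p = 0.121), and after correction for length and GC content with a smaller one (−0.07, adjusted p = 0.331). It was also lost without untreated b (−0.13, adjusted p = 0.157) and without lower dose a (−0.13, adjusted p = 0.161). That of INSR was lost without untreated b (−0.21, adjusted p = 0.0953). CXCR4 passed after the correction (−0.13, adjusted p = 0.0251) and without untreated a (−0.14, adjusted p = 0.0463). RPL10A, the protein that carries the tag, had 1544 ± 19 CPM in untreated cells and 1542 ± 28 CPM at the lower dose (adjusted p = 0.968), and passed after the correction (−0.14, adjusted p = 1.15e-06).

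Among the other genes with the largest rises were SFTA1P (0.67 ± 0.07), POPDC3 (0.59 ± 0.10). Several noncoding genes also rose, LOC100128191 (TMPO-AS1, 0.72 ± 0.09), LOC100128881 (VPS9D1-AS1, 0.66 ± 0.15), LOC439949 (PRKCQ-AS1, 0.63 ± 0.13), LOC100506994 (PTPRG-AS1, 0.63 ± 0.13) and LOC728190 (NUTM2A-AS1, 0.60 ± 0.09). These antisense genes cannot be told from their partner genes if strand was not used in counting. LOC730755 (KRTAP2-3, 0.62 ± 0.08), a keratin-associated protein gene, belongs to a family of near-identical copies and is uncertain. Falls included the extracellular matrix gene FBN1, fibrillin-1 (−0.62 ± 0.06), the cytochrome P450 gene CYP2S1 (−0.67 ± 0.12) and VASN (−0.65 ± 0.07). OLFML2A (−0.61 ± 0.08), RASL11A (−0.58 ± 0.11) and the placental alkaline phosphatase ALPP (−0.59 ± 0.07), which has close paralogs, fell as well. MTRNR2L2 (−0.60 ± 0.10) is a nuclear copy of mitochondrial sequence and is uncertain.

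The mRNAs of ribosomal proteins and translation factors that begin with a 5' terminal oligopyrimidine (TOP) tract rose as a list. Of them, 70 of 87 tested rose, 6 fell and 11 did not pass (72 and 6 adjusted over the list alone). The median log2 fold change was 0.18, with examples RPS21 (0.38 ± 0.03), RPL41 (0.35 ± 0.03), RPL37 (0.34 ± 0.03) and RPL32 (0.31 ± 0.03). Camera gave the list an adjusted p of 3.56e-14, and adjusted p = 0.347 with an estimated correlation. After correction for length and GC content the median was 0.06 (adjusted p = 0.000179), and RPS21 had 0.20 and RPL41 0.17. Of 40 nucleolar ribosome biogenesis factors, 12 rose and 0 fell (12 and 0 adjusted over the list alone). The rises were led by NOP16 (0.42 ± 0.05), NHP2 (0.23 ± 0.03, or 0.14 after the correction) and WDR74 (0.16 ± 0.04). The list had a camera adjusted p of 0.0154 and adjusted p = 0.347 with an estimated correlation. Regulators of apoptosis rose in 12 of 28 cases and fell in 2 (13 and 3 adjusted over the list alone). The risers included the inhibitors BIRC2 (0.31 ± 0.04) and BIRC3 (0.39 ± 0.07) and the BH3-only gene PMAIP1 (0.30 ± 0.04), while BMF, another BH3-only gene, fell (−0.48 ± 0.13). This list had a camera adjusted p of 0.0271, adjusted p = 0.347 with an estimated correlation, and 0.0548 without untreated b.

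The list of mitochondrially encoded mRNAs and nuclear noncoding RNAs held no tested mitochondrial gene. Of the members that were tested, 5 of 10 rose and 0 fell (6 and 1 adjusted over the list alone). The list had a camera adjusted p of 0.00409 and adjusted p = 0.347 with an estimated correlation. The risers were the snoRNA host genes SNHG1 (0.52 ± 0.04), SNHG8 (0.41 ± 0.04), SNHG5 (0.40) and GAS5 (0.26 ± 0.04), which are spliced and exported, and TUG1 (0.13 ± 0.03). GAS5 missed the threshold after correction for length and GC content (0.09, adjusted p = 0.0546), and TUG1 did so without untreated a (adjusted p = 0.0815) and without lower dose b (0.0590). After the same correction the list's median moved from 0.26 to 0.15 (adjusted p = 0.0165) and SNHG8 to 0.24.

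Of 28 genes of mesenchymal and epithelial state, 19 fell and 1, SNAI2 (0.20 ± 0.04), rose (20 and 1 adjusted over the list alone). Fibronectin FN1 (−0.41 ± 0.03), vimentin VIM (−0.31 ± 0.03), THBS1 (−0.32 ± 0.03) and LOXL2 (−0.30 ± 0.03) were among the falls, and the epithelial keratins KRT8 (−0.20) and KRT18 (−0.24) also fell. Camera gave this list an adjusted p of 6.39e-05, and adjusted p = 0.347 with an estimated correlation. Of 36 SREBP targets of cholesterol and fatty acid synthesis, 21 fell and 1 rose (22 and 2 adjusted over the list alone). Those that fell included SREBF1 (−0.47 ± 0.05), DHCR7 (−0.26 ± 0.03) and FASN (−0.23 ± 0.03, or −0.09 after correction for length and GC content). The SREBP list had a camera adjusted p of 0.000254 and adjusted p = 0.378 with an estimated correlation. Of 35 HIF target and glycolysis genes, 20 fell and 1, VEGFA (0.24 ± 0.03), rose (20 and 1 adjusted over the list alone). Falls included the glucose transporter SLC2A1 (−0.32 ± 0.03), NDRG1 (−0.35 ± 0.03) and PKM2 (PKM, pyruvate kinase, −0.25 ± 0.03). This list had a camera adjusted p of 0.00019 and adjusted p = 0.347 with an estimated correlation.

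FOXO target genes, which are transcribed when signalling through insulin-type receptors is low, fell in 15 of 33 cases and rose in 1 (15 and 1 adjusted over the list alone). Examples were CAT (−0.33 ± 0.04), CITED2 (−0.18 ± 0.03), YPEL3 (−0.31 ± 0.07) and ERBB3 (−0.49 ± 0.11). Of 12 tested ligands, receptors and binding proteins of the CXCL12 and IGF1 systems, 7 fell and 0 rose (8 and 0 adjusted over the list alone). Among them were IGF2R (−0.45 ± 0.03) and the binding proteins IGFBP1 (−0.37 ± 0.03) and IGFBP4 (−0.15 ± 0.03). Camera gave FOXO targets an adjusted p of 0.000764 and the ligand and receptor list 0.00119, and adjusted p = 0.347 with an estimated correlation for both. CXCR7 (ACKR3), CXCL12 and IGF1 had 0 to 3 reads in each library and were not tested. Lysosome and autophagy genes fell in 17 of 31 cases and rose in 3 (17 and 4 adjusted over the list alone), with CTSD (−0.31 ± 0.03) and NPC1 (−0.39 ± 0.04). Heat shock and endoplasmic reticulum chaperones fell in 15 of 25 and rose in 3 (17 and 3 adjusted over the list alone), with HSP90B1 (−0.40 ± 0.03) and HSPA5 (−0.31 ± 0.03). Both lists had a camera adjusted p of 0.00119 and adjusted p = 0.347 with an estimated correlation.

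Genes of G2 and mitosis fell in 17 of 36 cases and rose in 4 (21 and 4 adjusted over the list alone), with ASPM (−0.38 ± 0.04) and TOP2A (−0.23 ± 0.03). They had a camera adjusted p of 0.00148 and adjusted p = 0.347 with an estimated correlation. Interferon-stimulated genes fell in 12 of 32 cases and rose in 1 (12 and 1 adjusted over the list alone), with STAT2 (−0.51 ± 0.06) and IFIT3 (−0.30 ± 0.04). Genes linked to bone metastasis fell in 8 of 14 and rose in 1 (8 and 1 adjusted over the list alone). Here CTGF (CCN2, −0.26 ± 0.03) and IL11 (−0.21 ± 0.03) fell and FGF5 (0.54 ± 0.05) rose. Their camera adjusted p values were 0.00266 and 0.00409, and adjusted p = 0.347 with an estimated correlation for each. The 7 remaining lists did not pass. They were ERK output genes (10 rose and 7 fell of 27, adjusted p = 0.265), SRF-MRTF and YAP targets (5 and 6 of 22, 0.269) and G1/S genes (10 and 2 of 40, 0.107, or 0.0164 after correction for length and GC content). The others were NF-kB targets and cytokines (3 and 3 of 26, 0.314), immediate-early factors (5 and 4 of 25, 0.970), ATF4 targets (8 and 8 of 31, 0.947) and markers of other cell types (0 and 2 of 6, 0.477). Adjusted over these lists alone, in that order, 12 rose and 8 fell, 5 and 7, 9 and 2, 2 and 3, 5 and 4, 8 and 8, and 0 and 2. For the immediate-early list and the ATF4 list the mean, 0.02 for each, differed in sign from the median and the test.

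At the lower dose 4418 genes passed the threshold, 2262 up and 2156 down, with a median absolute log2 fold change of 0.20. Of these genes, 103 (54 up, 49 down) changed at least 1.5-fold and 30 at least 2-fold. DESeq2 called 2563. Of the 21 lists, 14 passed with the preset correlation (4 up, 10 down), 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 15 with fry.

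The second comparison asks the same of the higher dose (300 ng/mL CXCL12 with 100 ng/mL IGF1). YPEL3, a growth-restraining FOXO target, fell by 65.0%, from 21.3 ± 1.1 to 7.43 ± 0.48 CPM (SD, n = 2; log2 fold change −1.51 ± 0.08, edgeR adjusted p = 8.91e-23). PDCD4, an inhibitor of the translation initiation helicase eIF4A, fell by 59.1%, from 60.0 ± 0.69 to 24.5 ± 0.63 CPM (adjusted p = 5.48e-29). SNHG1, a snoRNA host gene, rose 2.21-fold, from 68.3 ± 3.6 to 151 ± 2.8 CPM (adjusted p = 1.41e-32). NOP16, a nucleolar ribosome assembly factor, rose 1.85-fold, from 33.9 ± 0.25 to 62.8 ± 0.71 CPM. Of the receptors, CXCR4 fell by 28.0% (−0.47 ± 0.05, adjusted p = 6.65e-12), IGF1R fell by 37.2% (−0.67 ± 0.06, adjusted p = 1.71e-14) and INSR fell by 42.5% (−0.80 ± 0.08, adjusted p = 7.25e-12).

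**Figure D1:**
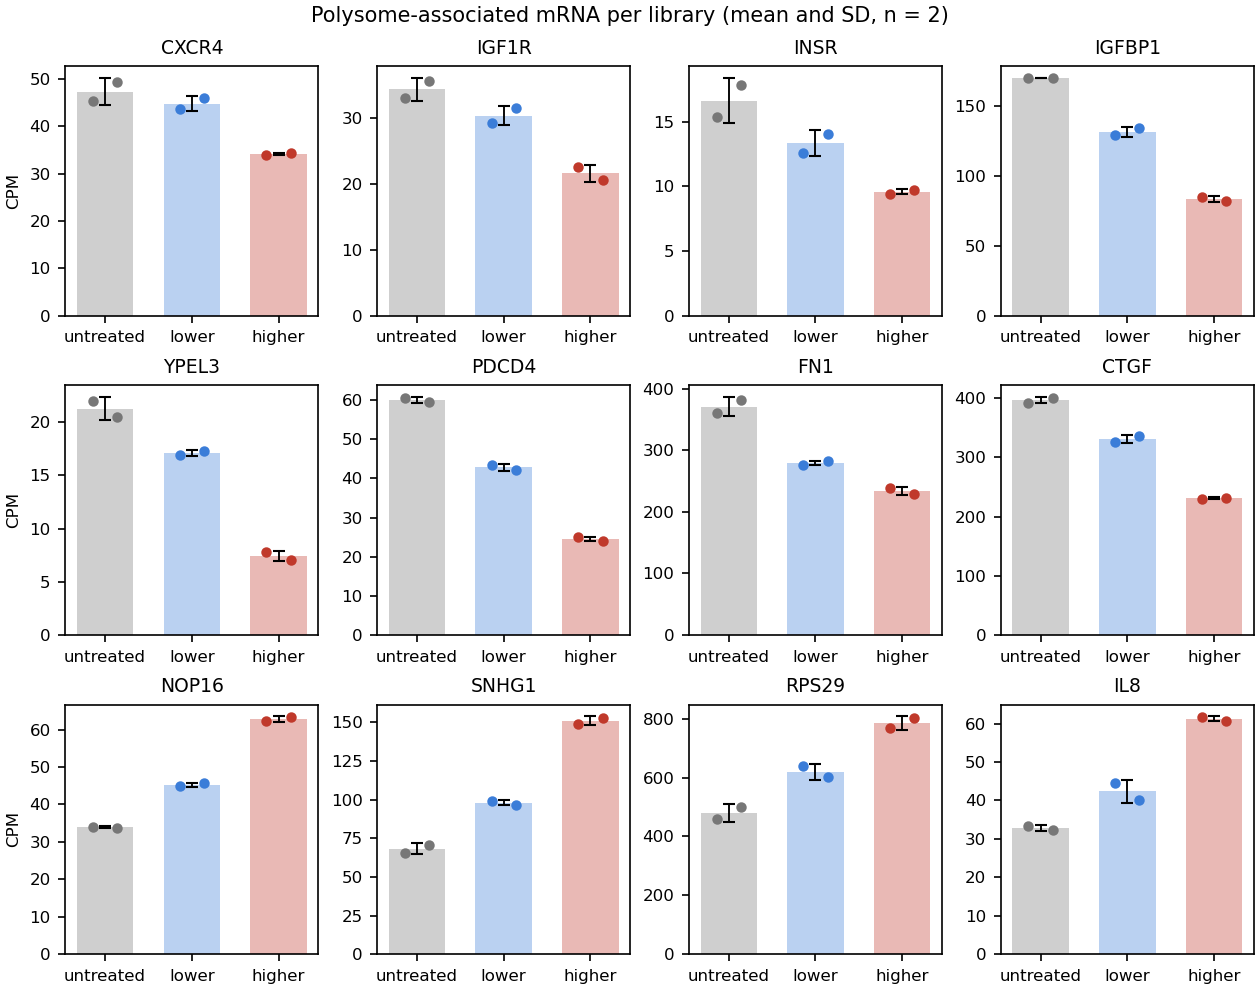
CPM (y axis) of 12 genes by condition; bars are means, error bars SD and points the 2 libraries of a condition. INSR went from 16.6 CPM in untreated cells to 9.58 CPM at the higher dose and SNHG1 from 68.3 to 151 CPM, with the lower dose between them.

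Further large rises were LOC100128881 (VPS9D1-AS1, 1.47 ± 0.13), the snoRNA host genes LOC388796 (SNHG17, 1.17 ± 0.07) and C7orf40 (SNHG15, 1.01 ± 0.07), LOC730755 (KRTAP2-3, 1.15 ± 0.08) and FAM86A (EEF2KMT, 1.08 ± 0.08), a methyltransferase of an elongation factor. They also included the AP-1 family factor BATF3 (0.94 ± 0.10), the mitochondrial import chaperone TIMM9 (0.94 ± 0.05), LOC100506994 (PTPRG-AS1, 0.94 ± 0.12) and FGF1 (0.93 ± 0.11). FAM86A has several pseudogenes and paralogs, and it is uncertain for that reason, as are KRTAP2-3 and the antisense genes. Further large falls were PBXIP1 (−1.46 ± 0.06), the ubiquitin ligase adaptor KLHL24 (−1.45 ± 0.08), JUP (−1.34 ± 0.07) and the autophagy receptor CALCOCO1 (−1.31 ± 0.07). RCSD1 (−1.26 ± 0.08), the receptor ERBB3 (−1.25 ± 0.12), the cyclin-dependent kinase inhibitor CDKN1C (−1.22 ± 0.11) and STAT2, a mediator of interferon signalling (−1.19 ± 0.07), fell too. RPL10A had 1544 ± 19 CPM in untreated cells and 1617 ± 5.7 CPM at the higher dose (0.07 ± 0.03, adjusted p = 0.0238). Its own and tagged copies cannot be separated by gene counts. This call was lost without untreated a (adjusted p = 0.162), higher dose a (0.138) or higher dose b (0.0933). After correction for length and GC content the value was −0.12 (adjusted p = 3.70e-06).

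Of the 33 FOXO targets, 22 fell, 4 rose and 7 did not pass (22 and 4 adjusted over the list alone), with a median of −0.44. Falls included HBP1 (−1.03 ± 0.07), CCNG2 (−0.79 ± 0.05) and CITED2 (−0.38 ± 0.03). The 4 rises were SESN1 (0.31), GADD45A (0.27), BCL2L11 (0.22) and BNIP3 (0.13), all described as FOXO targets in other settings. Camera gave FOXO targets an adjusted p of 7.20e-05, and adjusted p = 0.256 with an estimated correlation. Among ligands, receptors and binding proteins, 9 of 12 fell and 0 rose (9 and 0 adjusted over the list alone). IGFBP1, a secreted IGF binding protein repressed by insulin, fell from 170 to 83.7 CPM (−1.02 ± 0.03). IGF2R had −0.75 ± 0.03, and IGFBP4 and IGFBP7 had −0.31 ± 0.03. This list had a camera adjusted p of 0.000253 and adjusted p = 0.256 with an estimated correlation. Lysosome and autophagy genes fell in 25 of 31 cases, and 2, FLCN (0.22) and ATP6V0E1 (0.12), rose (25 and 2 adjusted over the list alone). Falls included the cholesterol transporter NPC1 (−0.68 ± 0.04), the protease cathepsin D gene CTSD (−0.49 ± 0.03) and CTSA (−0.45 ± 0.03). Their camera adjusted p was 8.50e-06, and adjusted p = 0.256 with an estimated correlation.

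Nucleolar ribosome biogenesis factors rose in 39 of 40 cases and fell in 0 (39 and 0 adjusted over the list alone). Their median was 0.31, with examples RRP9 (0.60 ± 0.04), GRWD1 (0.48 ± 0.04) and DKC1, the pseudouridine synthase dyskerin (0.42 ± 0.03). Camera gave them an adjusted p of 4.63e-11, and adjusted p = 0.256 with an estimated correlation. TOP mRNAs rose in 73 of 87 cases, fell in 9 and did not pass in 5 (73 and 11 adjusted over the list alone), with a median of 0.37. RPS29 rose from 479 ± 30 to 785 ± 23 CPM (0.71 ± 0.03), and RPS21 (0.67 ± 0.03), RPS28 (0.64 ± 0.03) and RPL37 (0.63 ± 0.03) rose likewise. The poly(A)-binding protein gene PABPC1 (−0.45 ± 0.03) and the elongation factor EEF1A1 (−0.37 ± 0.03) fell. For TOP mRNAs camera gave an adjusted p of 6.14e-13, and adjusted p = 0.334 with an estimated correlation. After correction for length and GC content the median was 0.20, with 64 rises and 13 falls (adjusted p = 2.56e-07), and RPS29 and RPS21 each had 0.44. Within this list the change followed coding length. Members under 600 nt rose in 54 of 55 cases and fell in 1 (RPLP1, −0.10), with a median of 0.44. The 21 members of 600 nt or more and under 1000 nt had a median of 0.20, and the 11 members of 1000 nt or more, of which 3 rose and 5 fell, had a median of −0.05.

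**Figure D2:**
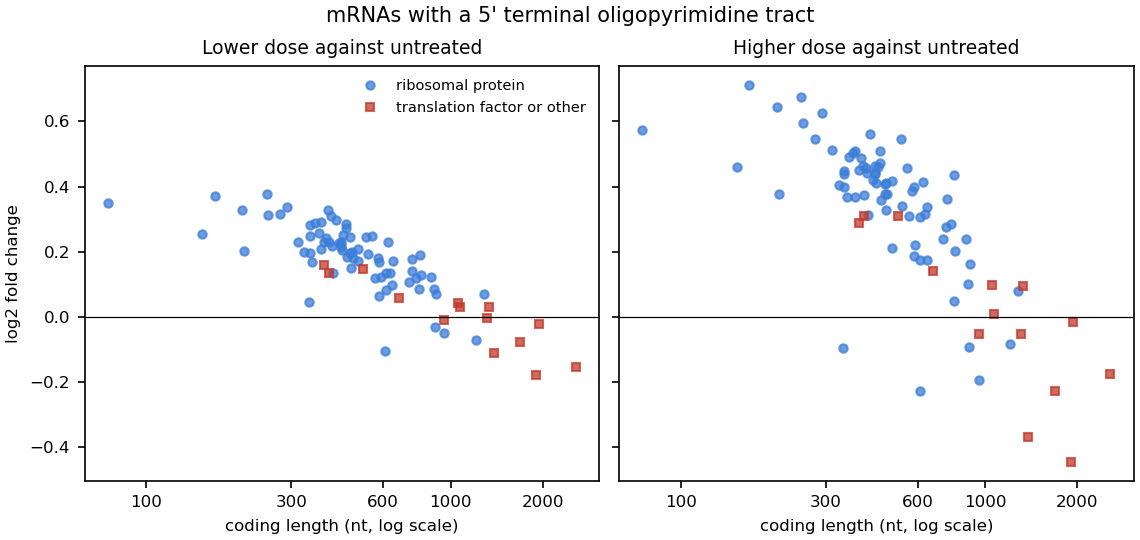
Log2 fold change (y axis) against coding length (x axis, nucleotides, log scale) of the 87 tested TOP mRNAs, at the lower dose (left) and the higher dose (right); each point is a gene, blue circles ribosomal proteins and red squares other genes. Points decline with length, with a Spearman rho across genes of −0.82 at the lower dose and −0.79 at the higher dose.

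Genes of G1/S and DNA replication rose in 22 of 40 cases and fell in 3 (23 and 3 adjusted over the list alone). GINS2 (0.55 ± 0.04), EXO1 (0.53 ± 0.04), the phosphatase CDC25A (0.53 ± 0.05) and the origin licensing factor CDC6 (0.32 ± 0.03) rose, and FEN1 (−0.17) and RRM1 (−0.11) were among those that fell. G2 and mitotic genes fell in 24 of 36 cases and rose in 4 (24 and 4 adjusted over the list alone). KIF20A (−0.53 ± 0.03), the checkpoint kinase BUB1 (−0.53 ± 0.04), ASPM (−0.52 ± 0.04) and topoisomerase TOP2A (−0.46 ± 0.03) fell, whereas CENPA (0.27), UBE2C (0.20), CKS2 (0.18) and BIRC5 (0.18) rose. G1/S genes had a camera adjusted p of 0.0014, and adjusted p = 0.256 with an estimated correlation. G2 and mitotic genes had a camera adjusted p of 0.000997, and adjusted p = 0.334 with an estimated correlation.

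In the list of mesenchymal and epithelial state genes, 21 of 28 fell and 2 rose, SNAI2 (0.32 ± 0.04) among them (21 and 2 adjusted over the list alone). Fibronectin FN1 (371 ± 15 to 234 ± 6.6 CPM, −0.67 ± 0.03), thrombospondin THBS1 (−0.59 ± 0.03) and the lysyl oxidase LOXL2 (−0.55 ± 0.03) fell. The protease MMP14 (−0.53 ± 0.03) and the collagen COL4A1 (−0.85 ± 0.06) also fell, as did the epithelial keratins KRT8 (−0.25) and KRT18 (−0.34). Camera gave the list an adjusted p of 6.21e-06, and adjusted p = 0.256 with an estimated correlation. Of the 14 genes linked to bone metastasis, 11 fell and 3 rose (11 and 3 adjusted over the list alone). CTGF (396 ± 5.2 to 231 ± 1.1 CPM, −0.78 ± 0.03), IL11 (−0.70 ± 0.03) and MMP1 (−0.41 ± 0.03) fell. The growth factor FGF5 (0.90 ± 0.05), parathyroid hormone-like hormone PTHLH (0.71) and PTGS2 (0.64) rose. This list had a camera adjusted p of 0.011 and adjusted p = 0.256 with an estimated correlation. Of 35 HIF target and glycolysis genes, 19 fell and 7 rose (20 and 8 adjusted over the list alone). NDRG1 (−0.75 ± 0.03), SLC2A1 (−0.62 ± 0.03) and PKM2 (−0.39 ± 0.03) fell and VEGFA (0.55 ± 0.03) rose. The HIF list had a camera adjusted p of 0.0447 and adjusted p = 0.538 with an estimated correlation. This call was lost with the replicate block (adjusted p = 0.0606). It was also lost without untreated a (median −0.147), higher dose a (−0.173) or higher dose b (−0.146).

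NF-kB targets and cytokines rose in 14 of 26 cases and fell in 5 (15 and 5 adjusted over the list alone). The chemokine IL8 (CXCL8, 32.8 ± 0.84 to 61.2 ± 0.65 CPM, 0.90 ± 0.05) and BIRC3 (0.91 ± 0.07) rose, as did IL6 (0.60 ± 0.13). The 5 that fell were CSF1 (−0.80 ± 0.04), IL11, the adhesion molecule ICAM1 (−0.56), NFKBIA (−0.24) and NFKB2 (−0.13). This list had a camera adjusted p of 0.0339, and adjusted p = 0.256 with an estimated correlation. The call was lost with at least 5 CPM in 2 libraries (median 0.16, adjusted p = 0.149), with limma voom (0.139) and without untreated b (0.117). Interferon-stimulated genes fell in 13 of 32 cases and rose in 3 (13 and 3 adjusted over the list alone). IFIT2 (−0.59 ± 0.05), DDX58 (RIGI, −0.56 ± 0.05) and IFIT3 (−0.49 ± 0.04) fell, and IFI44L (0.90 ± 0.37), IFI44 (0.21) and ISG15 (0.19) rose. Their camera adjusted p was 0.0278, adjusted p = 0.431 with an estimated correlation, and 0.0768 without untreated a. Their median of −0.13 moved to −0.21 after correction for length and GC content, to −0.08 with at least 5 CPM in 2 libraries, to −0.19 without higher dose a and to −0.07 without higher dose b.

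The list of nuclear noncoding RNAs rose through the snoRNA host genes SNHG1, SNHG8 (0.80 ± 0.04), SNHG12 (0.70 ± 0.10), SNHG5 (0.66 ± 0.08) and GAS5 (0.46 ± 0.04, or 0.22 after correction for length and GC content) and through RPPH1, the RNA of ribonuclease P (1.06 ± 0.18). NEAT1, a nuclear-retained RNA, fell (−0.52 ± 0.10), and 3 of the list's 10 tested members did not pass (6 up and 1 down adjusted over the list alone). Its median was 0.56, or 0.33 after that correction. It had a camera adjusted p of 0.0447, and adjusted p = 0.395 with an estimated correlation. This p was 0.0539 without a filter, 0.0570 with at least 5 CPM in 2 libraries and 0.0932 with the replicate block. The call was also lost without untreated b (median 0.60), higher dose a (0.59) or higher dose b (0.52).

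The 8 other lists did not pass at the higher dose. Of 27 ERK output genes 14 rose and 9 fell (adjusted p = 0.476), with PHLDA2 (0.55 ± 0.03), ETV1 (−0.66 ± 0.04), EPHA2 (−0.44 ± 0.03) and the phosphatase DUSP4 (−0.36 ± 0.03, or −0.23 after correction for length and GC content). Of 25 immediate-early factors 11 rose and 4 fell (0.129), with KLF4 (0.75 ± 0.06), JUN (0.51 ± 0.04), FOSL1 (0.24 ± 0.03) and KLF2 (−0.73 ± 0.06), while MYC had −0.02 ± 0.03 (adjusted p = 0.648). Of 22 SRF-MRTF and YAP targets 8 rose and 10 fell (0.408), with ANKRD1 (−0.95 ± 0.03), CTGF and CYR61 (CCN1, −0.62 ± 0.03) lower and the actin gene ACTG1 (0.46 ± 0.03) higher. Of 36 SREBP targets 10 rose and 16 fell (0.346), with ACSS2 (−0.41 ± 0.04) and TMEM97 (0.52 ± 0.03). Of 31 ATF4 targets 15 rose and 7 fell (0.129), with CEBPB (0.70 ± 0.04), ATF5 (0.49 ± 0.04) and ATF4 (0.44 ± 0.03). This list passed after correction for length and GC content (0.0425). Of 28 apoptosis regulators 13 rose and 5 fell (0.0967, or 0.0292 with limma voom), with PMAIP1 (0.59 ± 0.04), BIRC2 (0.55 ± 0.04) and BAK1 (0.40 ± 0.04) higher and BMF (−1.48 ± 0.16) lower. Of 25 chaperones 7 rose and 14 fell (0.168), with HSP90B1 (−0.63 ± 0.03), BAG3 (−0.46 ± 0.03), SDF2L1 (0.70 ± 0.05) and HSPE1 (0.49 ± 0.03). Of 6 tested markers of other cell types, CD14 (−0.77 ± 0.09) and PDGFRB (−0.88 ± 0.13) fell. PECAM1 (−0.47 ± 0.23) and the others did not pass, and the list had an adjusted p of 0.248. Its median of −0.62 moved to −0.35 without higher dose a and to 0.09 without a filter on low counts. Adjusted over these lists alone, in that order, 14 rose and 10 fell, 11 and 4, 8 and 10, 10 and 17, 15 and 7, 13 and 5, 7 and 15, and 0 and 2.

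**Figure D3:**
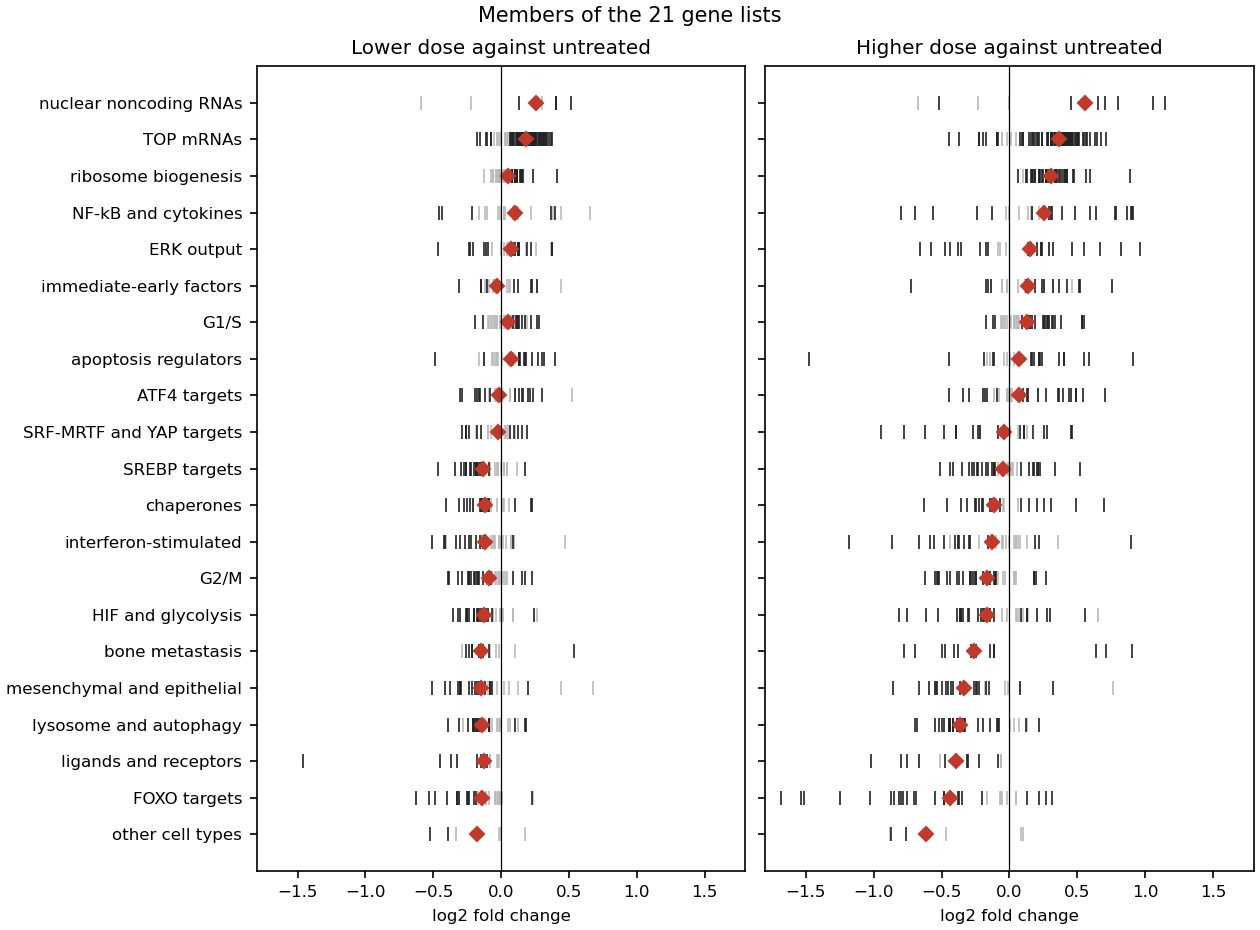
Log2 fold change (x axis) of every tested member of the 21 gene lists (y axis) at the lower dose (left) and the higher dose (right); black ticks are members that passed the test, grey ticks those that did not, and red diamonds the list medians. At the higher dose the medians run from −0.62 for the 6 tested markers of other cell types (−0.35 without higher dose a, 0.09 without a filter on low counts) to 0.56 for the list of nuclear noncoding RNAs. In that list snoRNA host genes and RPPH1 rose, NEAT1 fell and 3 of 10 tested members did not pass.

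At the higher dose 7626 genes passed, 3805 up and 3821 down, which was 56.3% of those tested, with a median absolute log2 fold change of 0.29. Of these, 935 (382 up, 553 down) changed at least 1.5-fold and 162 at least 2-fold. TMM centred the fold changes, with a median over all tested genes of −0.0008. The near-equal split of calls therefore does not speak to a shift shared by most genes. DESeq2 and RLE size factors also take most genes as unchanged. Of the 21 lists 13 passed with the preset correlation (5 up, 8 down), 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 19 with fry.

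The third comparison tested the doses against each other. YPEL3 fell by 56.6% from the lower to the higher dose (17.1 ± 0.30 to 7.43 ± 0.48 CPM, n = 2; −1.20 ± 0.09, edgeR adjusted p = 6.20e-17). It was followed by KLHL24 (−0.91 ± 0.09), METTL7A (TMT1A, −0.83 ± 0.12), PDCD4 (−0.80 ± 0.05) and CALCOCO1 (−0.80 ± 0.07). LOC100128881 (VPS9D1-AS1, 0.81 ± 0.12), LOC388796 (SNHG17, 0.68 ± 0.07), C16orf55 (SPATA33, 0.66 ± 0.09), SNHG1 (0.62 ± 0.03) and FAM86A (EEF2KMT, 0.62 ± 0.08) rose most. CXCR4 (−0.39 ± 0.05, adjusted p = 8.36e-09), IGF1R (−0.49 ± 0.06) and INSR (−0.48 ± 0.09) were lower at the higher dose than at the lower. RPL10A had 0.07 ± 0.03 (adjusted p = 0.0327), a call lost without lower dose b (0.292), higher dose a (0.181) or higher dose b (0.130) and after correction for length and GC content (0.674).

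Ribosome biogenesis factors rose between the doses in 39 of 40 cases and fell in 0 (39 and 0 adjusted over the list alone). The median was 0.25, with examples RRP9 (0.46 ± 0.04), BOP1 (0.32 ± 0.03) and DDX21 (0.31 ± 0.03). Camera gave them an adjusted p of 5.37e-16, and adjusted p = 0.179 with an estimated correlation. TOP mRNAs rose in 68 of 87 cases and fell in 6 (69 and 7 adjusted over the list alone). These had a camera adjusted p of 6.08e-12 and adjusted p = 0.344 with an estimated correlation. G1/S genes rose in 14 of 40 and fell in 0 (14 and 0 adjusted over the list alone), with RRM2 (0.20 ± 0.03). ATF4 targets rose in 14 of 31 and fell in 3 (14 and 3 adjusted over the list alone), with DDIT4 (0.29 ± 0.03) and MTHFD2 (0.29 ± 0.04). NF-kB targets rose in 9 of 26 and fell in 2 (9 and 2 adjusted over the list alone), the latter being CSF1 (−0.37 ± 0.04) and IL11 (−0.49 ± 0.03). Immediate-early factors rose in 10 of 25 and fell in 4 (10 and 4 adjusted over the list alone), with EGR1 (0.42 ± 0.06) and IER2 (0.24 ± 0.03). In that order the camera adjusted p values were 5.80e-05, 0.00495, 0.0159 and 0.0216, and adjusted p = 0.214, 0.214, 0.214 and 0.218 with an estimated correlation. The NF-kB call was lost with at least 5 CPM in 2 libraries (median 0.17 to 0.06, adjusted p = 0.0551) and with limma voom (0.0527). SREBP targets, which had fallen at the lower dose, rose in 13 of 36 cases and fell in 4 (13 and 4 adjusted over the list alone). Rises included the fatty acid synthase FASN (543 ± 14 to 702 ± 21 CPM, 0.37 ± 0.03), MVD (0.31 ± 0.03) and HMGCS1 (0.23 ± 0.03). Their median was 0.05, with a camera adjusted p of 0.0185 and adjusted p = 0.615 with an estimated correlation. Without higher dose a the median was 0.03 (adjusted p = 0.0712).

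Lists that fell between the doses were FOXO targets (18 of 33 fell and 4 rose; 19 and 4 adjusted over the list alone), ligands, receptors and binding proteins (8 of 12 and 0; 8 and 0) and lysosome and autophagy genes (22 of 31 and 1; 23 and 1). Mesenchymal and epithelial genes (18 of 28 and 3; 19 and 3), G2 and mitotic genes (18 of 36 and 2; 19 and 2) and bone metastasis genes (8 of 14 and 3; 8 and 3) also fell. Their camera adjusted p values were, in that order, 9.79e-05, 0.000483, 2.31e-07, 1.64e-05, 0.00495 and 0.0443, and adjusted p = 0.179, 0.218, 0.214, 0.214, 0.405 and 0.30 with an estimated correlation. Examples were HBP1 (−0.78 ± 0.07), GABARAPL1 (−0.54 ± 0.06), IGFBP1 (−0.65 ± 0.03) and WIPI1 (−0.42 ± 0.04). Further examples were TGFB2 (−0.44 ± 0.04), CD44 (−0.26 ± 0.03), BUB1 (−0.31 ± 0.04) and MMP1 (−0.32 ± 0.03). The proliferation marker MKI67, in the G2 and mitotic list, rose (0.22 ± 0.03). The bone metastasis call was lost without a filter (adjusted p = 0.109) and with only the 4 libraries compared (0.0597). It was lost too with the replicate block (0.0555) and after correction for length and GC content (0.121). Leaving out each of the 6 libraries in turn also lost it (medians −0.153 to −0.082). The remaining lists did not pass. Among them were ERK output genes (10 rose and 7 fell, adjusted p = 0.884), SRF-MRTF and YAP targets (6 and 8, 0.512) and HIF and glycolysis genes (8 and 12, 0.646). Interferon-stimulated genes (2 and 11, 0.164) and apoptosis regulators (7 and 3, 0.304) also missed the threshold. So did chaperones (7 and 5, 0.164, or 0.0484 without higher dose b), nuclear noncoding RNAs (5 and 3, 0.0795, or 0.00651 with limma voom and 0.0321 without lower dose a) and markers of other cell types (0 and 2, 0.134, or 0.0438 without higher dose b). The fall of PDGFRB (−0.35 ± 0.14, adjusted p = 0.0451) was lost under 7 of the alternatives (−0.21 without higher dose b) and that of CD14 (−0.37 ± 0.10) without lower dose b (0.106). Adjusted over these lists alone, in that order, 11 rose and 10 fell, 7 and 8, 10 and 15, 2 and 11, 7 and 3, 8 and 5, 6 and 3, and 0 and 2. For ERK output genes the median and mean, 0.03 each, lay above 0 and the test pointed down.

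Between the doses 4612 genes passed, 2221 up and 2391 down, and 180 of them (64 up, 116 down) changed at least 1.5-fold. DESeq2 called 2759 between the doses. Of the 21 lists 13 passed (7 up, 6 down), 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 16 with fry.

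The last comparison asks whether the doses changed the same genes. There were 4015 genes called at both doses in the same direction (2413 with DESeq2, and 67 with a fold of at least 1.5 at both) and 19 in opposite directions. Of the former, 2048 rose, SNHG1, FGF1 and NOP16 among them, and 1967 fell, YPEL3, IGFBP1 and FN1 among them. Independent lists of these sizes would share 635 up and 608 down. Simulated unchanged groups, set against the same simulated untreated libraries, shared 0.1 on average, a low value that follows from drawing no changes. Log2 fold changes at the doses correlated across genes at 0.76 against 0.50 simulated, had the same sign for 82.2% of genes against 66.7%, and had a covariance of 0.0547 against 0.00963. A split of the untreated libraries would leave 1 for each dose and none was made, so part of the excess in calls, correlation and sign may come from the shared controls. Of the 4015 genes, 2258 moved further in the same direction between the doses, 11 moved back and 1746 did not pass between the doses. A further 3592 genes were called at the higher dose and not at the lower, and 384 at the lower and not at the higher.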

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

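Tests with the length and GC correction, the fold minimum and thinned libraries were chosen only after the results were seen. With DESeq2, 2563 genes were called at the lower dose, 2759 between the doses and 2413 at both doses in the same direction. All but 1 of the genes it called in each comparison were also called by edgeR. In simulated counts it recovered 32% of the genes with the smallest change where edgeR recovered 58%. A fold of at least 1.5 left 103 genes at the lower dose, 935 at the higher, 180 between the doses and 67 at both. Camera with an estimated correlation called 0 of 21 lists in each comparison, where fry called 15, 19 and 16. Fry does not compare a list with other genes, and 32.6% to 56.3% of tested genes were called, so many lists pass it. The estimated correlation rests on 3 residual degrees of freedom. All other settings, including each library left out, kept the counts of genes and lists called, and of genes called at both doses, within 1.5 times. Where 1 library is left out, its partner is assumed to vary like the other groups. The letters did not pair the libraries (correlations of deviations −0.04, 0.00 and −0.03); a fit with the replicate block called 4320, 7561 and 4516 genes and 14, 11 and 12 lists. After correction for length and GC content 4118, 7369 and 4572 genes were called, of which 3302, 6312 and 3976 were also called without it in the same direction and 1, 41 and 0 in the opposite one. Thinned to the smallest library, 7476 genes were called at the higher dose, 7344 of them also before thinning, but library sizes differ too little for this to show what depth limits. Medians of some uncalled lists changed sign, most of them near 0, and the cause was not tested. SRF-MRTF and YAP targets had, between the doses, 0.000576 with RLE size factors, 0.0258 without a filter, 0.0208 with at least 5 CPM in 2 libraries, and −0.0479 (without lower dose a) to 0.00949 (without lower dose b). At the higher dose they had 0.000865 with at least 5 CPM, 0.0218 after the correction, and −0.0618 (without untreated b) to 0.0466 (without untreated a), and at the lower dose −0.0640 to 0.00585 without the same libraries. ERK output genes between the doses had −0.0608 with at least 5 CPM, −0.0164 after the correction, and −0.0543 (without higher dose b) to 0.04997 (without higher dose a). ATF4 targets had 0.000364 at the lower dose after the correction, and markers of other cell types at the higher dose went from −0.62 to 0.0936 without a filter. RPL10A turned to −0.12 at the higher dose after the correction, and at the lower dose ran from −0.0219 (without lower dose a) to 0.0165 (without lower dose b). Of all other values of named genes, 4419 kept direction and side of the threshold, 26 lost and 3 gained a call; of those of lists, 853 kept both, 68 lost a call (40 with the estimated correlation) and 7 gained one.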

Other observations

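Gene families grouped by symbol were defined after the list results were seen, as were the snoRNA host group and the tests of length recovery shared by all mRNAs and of the order within the TOP list. At the higher dose 61 of 78 mitochondrial ribosomal protein genes rose and 2 fell (median log2 fold change 0.23), and 19 of 20 TIMM and TOMM genes of mitochondrial protein import rose and 0 fell (0.40), with TIMM9 at 0.94 ± 0.05 and TIMM10 at 0.51 ± 0.04. Of 10 RNA polymerase III subunits 8 rose and 1 fell. Of 16 integrins 13 fell and 1 rose (−0.40), with ITGB4 at −0.97 ± 0.03; of 10 laminins 7 fell and 2 rose (−0.51), with LAMB3 at −0.45 ± 0.03; of 27 plexins and semaphorins 16 fell and 1 rose; and of 20 HLA genes, which share reads, 11 fell and 0 rose. Of 21 such families 14 passed camera at the higher dose and 0 with an estimated correlation (adjusted p = 0.245 for each family named so far). After correction for length and GC content 7 of the 14, the same families, still passed and 7 lost their calls. Lost were translation initiation factors (adjusted p = 0.0587), protocadherins, collagens, the RNA exosome, ATP synthase, the proteasome and respiratory complex I (adjusted p = 0.974 for the last 2).

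Of 23 tested snoRNA host genes, 16 rose at the lower dose, 20 at the higher and 16 between the doses, and 0 fell in any of these comparisons, with medians of 0.36, 0.63 and 0.23. Camera p values, unadjusted, were 5.40e-10, 3.55e-09 and 1.61e-07, and 0.0647, 0.0727 and 0.0949 with an estimated correlation. Host genes outside the fixed lists included SNHG9 (1.57 ± 0.15), C17orf76-AS1 (SNHG29, 0.60 ± 0.03) and ZNFX1-AS1 (ZFAS1, 0.57 ± 0.04) at the higher dose.

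TOP mRNAs rose more the shorter their coding sequence (rho −0.79 across 87 genes, permutation p = 1e-04, the smallest that 10000 permutations give; −0.73 among 73 ribosomal proteins). Recovery that favours short mRNAs alike would raise matched genes as much. Members instead exceeded genes of like transcript length and level by a median of 0.246 (95% interval 0.218 to 0.304, or 0.289 when matched on coding length). The length slope between replicates was at most 0.137 times that between the higher dose and untreated cells. This bears only on variation from library to library, since recovery that differed by condition would leave replicates alike. Members were somewhat more abundant than their matched genes (median log2 CPM 9.85 against 9.45). The intervals in this paragraph and the next, and the permutation p, treat genes as independent and leave out differences between cultures. Other abundant genes had a length slope of −0.110 per doubling of coding length against −0.226 within the list, a ratio of 2.06 with intervals apart. The slopes cover unlike lengths, as 55 of the 87 members were under 600 nt, against 162 such other genes and 324 of 1000 nt or more. Most members of 1000 nt or more were also not ribosomal proteins. The trend of other genes may therefore account for part of the order within the list, and whether it accounts for all cannot be told. Reads shared with pseudogenes would spare the genes with few of them, but the 20 ribosomal protein genes with at most 3 named pseudogenes had a median of 0.410 (0.354 to 0.467). One hypothesis is that the treatment raised the share of TOP mRNAs on ribosomes. Alone it would not account for the 9 of 87 that fell at the higher dose, against 73 that rose. PABPC1 (−0.45) and EEF1A1 (−0.37) were among the falls. More of each mRNA in the cell, or a shift to heavier or lighter polysomes by length, stays open, since total RNA was not analysed here.

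The rise of snoRNA host genes exceeded that of genes of like length and level by a median of 0.529 (0.382 to 0.632), against short length as the whole cause. Carry-over of nuclear RNA, spliced or not, stays open. Hosts exceeded 5 nuclear-retained RNAs by 0.858, but the interval (−0.438 to 1.30) includes 0. With so few RNAs its lower bound rests on RPPH1, which rose (1.06 ± 0.18) at a mean of 2.34 CPM. NEAT1 fell (−0.52 ± 0.10), and TUG1 (−0.006), MALAT1 (−0.23) and KCNQ1OT1 (−0.68) did not pass. Several hosts carry a TOP tract and are degraded when translated, so a change in their ribosome association or in their decay may be what the pull-down shows, and neither was tested.

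Of the 4015 genes called at both doses in the same direction, 2258 moved further between the doses and 1746 did not pass there, and of 36 SREBP targets 21 fell at the lower dose and 13 rose between the doses. Independent offsets of each condition's cultures, as the only source, would make the change from untreated to lower dose and that from lower to higher dose covary below 0. In the 8 pairings of single libraries that share none the covariance across genes lay between 0.0142 and 0.0257, which argues against offsets alone. An offset of the lower dose cultures beside changes that grow with dose would still allow such values and stays open, also for the SREBP targets. Library sizes did not run with dose, since the treated libraries (28280141 to 28910985 reads) lay between the untreated ones. The share of reads in overlapping genes did rise with dose (untreated 1.87% and 1.90%, lower dose 1.98% and 1.97%, higher dose 2.06% and 2.08%). That of the 10 most abundant genes fell (4.88% and 4.77%, 4.61% and 4.56%, 4.34% and 4.32%). The shares outside annotated genes and without a unique position did not run with dose. Whether the shares that did came from changed genes or from processing was not tested. A processing order that ran with dose could make changes grow with dose and stays open, as the labels name no batch, beside a response that grows with the dose of the factors.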
